A study of Mus musculus with 18 samples.

How the data were processed

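The series holds 18 samples: 12 RNA-seq libraries in 4 groups of 3, 2 H3K36me3 ChIP-seq libraries and 4 whole-genome bisulfite libraries. Groups and replicate numbers were taken from the titles of the samples. Per the labels' protocols, HSPCs of bone marrow and C-Kit+ cells of leukemic spleens were sorted by flow cytometry, RNA libraries were made with the NEBNext Ultra RNA kit, ChIP libraries with antibody ab9050 and a KAPA kit, and bisulfite libraries with a lambda DNA spike-in. The choice of tests, gene lists, named genes and the first set of alternatives was made before the data were examined.

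Gene-level read counts were deposited by the authors as one raw table of 53946 genes, of which 20286 had no count in any library. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 and counted with HTSeq 0.9.1 on mm10, and the notes also name DESeq2 1.22.2, Trimmomatic, Bowtie2 2.2.9, SAMtools 1.7, MACS2 2.1.1.20160309, deepTools and Bismark 0.19.0. The FPKM table the authors deposited equals count divided by gene length and by the column total, with a largest relative difference of 0, so it carries no correction for composition. Every column of values was used. The peak lists deposited by the authors give each broad peak a fold enrichment, a score of 10 times the −log10 q, and the −log10 p and q, in the layout MACS2 writes; what served as input for the ChIP libraries and their depth are not given in the sources used here, and each list comes from 1 library. The tables of differentially methylated regions deposited by the authors give, per the file headers, the mean methylation of both sides as a fraction, their difference, a score summed over the region, the length and the number of CpG sites. The caller of these regions is not given in the sources used here, and the tables hold no coverage. Which side belongs to which library was taken from the order of the names of the tables and checked against identical regions that share a library.

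Symbols were taken from the deposited FPKM table, and 231 symbols stand for more than 1 gene identifier. Coordinates came from a RefSeq gene table of GRCm38.p6, the same build as mm10, matched by unique symbol for 36771 genes. That table gives no strand, exons or UTRs, so promoters were not defined. Whether the counting used strand is not given in the sources used here, so overlapping and antisense genes, and families such as the stefins, histones and ribosomal proteins with their processed copies, are uncertain.

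Differential expression was tested on the raw counts with edgeR 4.0.16 (R 4.3.3): TMM factors (0.798 to 1.25), filterByExpr over the 4 groups (16233 genes kept), 1 model over the 12 libraries with a mean per group and 8 residual degrees of freedom, and the robust quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05 and no fold threshold. The common biological coefficient of variation was 0.087. The SE of a log2 fold change is its size divided by the square root of F. CPM values of genes are counts per total of the tested genes times the TMM factor; those of Xist, the Y-linked genes and immunoglobulin segments, and the filter at 1 CPM, are per library total without TMM factors. A fold against a group with no counts was computed against a floor of 3 counts over the group. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, with adjustment over 69 tests, 23 lists in 3 comparisons. Of the calls made this way, those lost with an estimated correlation are named beside each list, and the others held. List members were counted from the gene test, and also adjusted over the list alone.

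The lists were erythroid genes, heme synthesis and iron, neutrophil granule and granulocyte, monocyte and macrophage, TLR4 and NF-kappaB response, stem cell, Hox-Meis program, megakaryocyte and platelet, mast cell with basophil and eosinophil, B cell, T and NK cell, dendritic cell, stroma and endothelium, interferon response, G2/M, S phase, H3K36 and DNA methylation, p53 response, immediate early and heat shock, mitochondrially encoded, cytosolic ribosomal proteins, glycolysis and hypoxia, and leukemia-associated genes. Some genes are in 2 lists, such as Flt3 and Meis1. Single values of some list members are not reported here. The named genes are Setd2, S100a8 and S100a9, which the study is about; the 8 that rose and the 8 that fell most among genes with an adjusted p below 0.05, a mean of at least 10 CPM in the higher group, no overlap between the libraries compared and an official symbol; and up to 4 members of each called list and 2 of each other list with the smallest p. The text prints part of them, and names some of the members that moved against their list, chosen after their values were seen.

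Peak lists were compared with bedtools 2.31.1, with an overlap of at least 1 bp. Intervals of shares are Wilson 95% intervals and, like the floor for counts, cover counting error only. The RNA of genes that lost or kept a peak was compared by a two-sided permutation test of the difference in medians with 100000 resamples, and the overlap of genes with regions and genes with RNA changes by Fisher's exact test, two-sided, over 12 tests, with a version stratified by tertiles of gene length (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 under Python 3.11.15; figures with matplotlib 3.10.9). The interval of the Setd2 fold change uses the normal approximation.

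The steps were tested on simulated counts drawn from the means and library sizes of the real ones. Of 50 genes changed 1.5-fold, 68% were recovered for NHD13 against WT (15817 genes), 64% for the KO label against NHD13 (15821 genes) and 64% for AML against the KO label (14916 genes); for 2-fold changes it was 86%, 86% and 78%, and for 1.2-fold changes 4%, 8% and 14%. Changes of 2-fold and less were therefore missed in part in the simulation, in which depth and replicate number were not varied. Far fewer genes were changed there than were called in the data. This makes the adjustment for multiple tests stricter, so recovery in the data may be higher. The changed genes were drawn only from genes above a minimum expected count, so recovery over all tested genes may be lower.

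Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, no filter, a filter at 1 CPM, the 6 libraries of a comparison alone, a replicate block, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a 2-fold threshold, each library left out in turn, fry and an estimated correlation for lists, and stricter peaks, regions and overlaps. A correction for gene length (an offset per library from a smooth fit of log2 CPM on log2 length) and fits without X and Y were added after the data were seen.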

Results

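Gene expression was measured by RNA-seq in 12 mouse libraries, 4 groups of 3. The WT libraries came from hematopoietic stem and progenitor cells (HSPCs) sorted out of C57BL/6 bone marrow. The NHD13 libraries came from HSPCs of mice with floxed Setd2 alleles and the NUP98-HOXD13 fusion transgene, which gives mice a myelodysplastic syndrome (MDS) that can turn into leukemia. Setd2 encodes the methyltransferase that trimethylates histone H3 at K36 (H3K36me3), and a further group of HSPC libraries is labelled NHD13/Setd2 KO, with deletion by Mx1-Cre. The AML libraries came from C-Kit+ spleen cells of such mice at the leukemia stage. H3K36me3 was profiled by ChIP-seq in 1 library of leukemia-stage spleen cells labelled NHD13 and 1 labelled NHD13/Setd2 KO. DNA methylation was profiled by whole-genome bisulfite sequencing in 4 libraries, 1 for each group of the RNA series.

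Total counts per library ran from 22115101 to 23767776 in WT, from 22243002 to 24766705 in NHD13, from 20436804 to 28127686 in the libraries labelled KO and from 18673704 to 20577958 in AML. The median coefficient of variation among genes with a mean of 10 CPM (counts scaled to the total of the tested genes in a library times its TMM factor) or more was 7.53% in WT, 7.0% in NHD13, 5.39% in the libraries labelled KO and 3.51% in AML. Every pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 1.97 to 30.4. It was highest for replicate 1 of WT against replicates 2 and 3 (30.4 and 29.3), which differed from each other by 4.01. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Mitochondrially encoded genes took 0.967% to 1.61% of the counts of a library. Log2 fold changes are given ± SE and CPM ± SD (n = 3).

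Setd2 (ENSMUSG00000044791; chromosome 9, 110532500 to 110618633 in mm10) was not detectably lower in the libraries labelled KO than in NHD13. Its level was 33.5 ± 1.72 CPM in NHD13 and 32.4 ± 2.91 CPM in the libraries labelled KO, a log2 fold change of -0.05 ± 0.08 (adjusted p = 0.685) with a 95% interval of -0.21 to 0.12. A fall of more than 13.7% lay outside that interval. A count over the whole gene cannot see the deletion of an exon, and which exons were floxed is not given in the sources used here, so these counts do not check the label. Each direction drawn between these groups rests on the labels alone. In WT, Setd2 stood at 42.1 ± 4.33 CPM, and it was lower in NHD13 (log2 -0.33 ± 0.08, adjusted p = 0.00213). In AML it stood at 183 ± 4.14 CPM, 5.66-fold above the libraries labelled KO (log2 2.50 ± 0.08, adjusted p = 1.64e-15; 1.61 with a correction for gene length that was added after the data were seen).

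**Figure D1:**
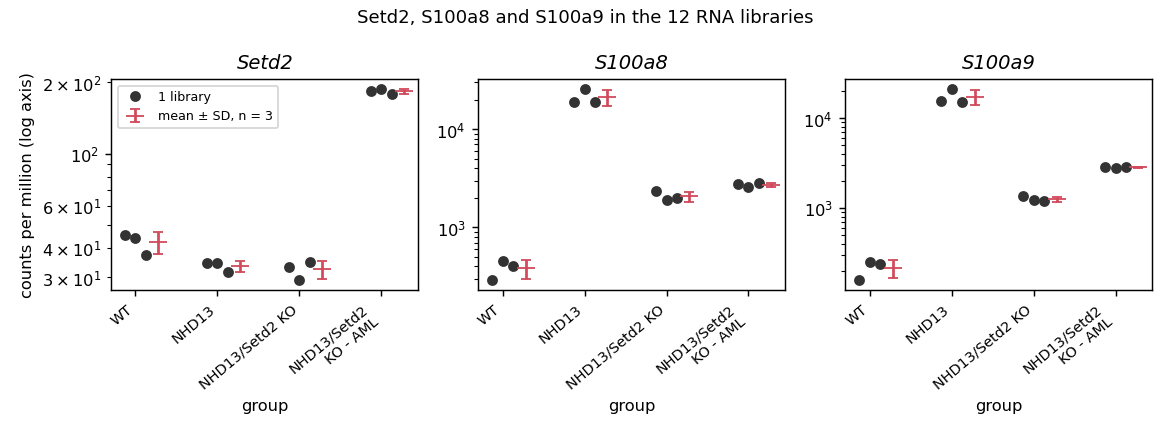
CPM (log axis) of Setd2, S100a8 and S100a9 in each of the 12 libraries, with the group mean and SD (n = 3). Setd2 is at similar levels in NHD13 and the libraries labelled KO (33.5 and 32.4 CPM), while S100a8 goes from 381 CPM in WT to 21169.8 CPM in NHD13 and 2072 CPM in the libraries labelled KO.

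The comparison of NHD13 with WT asked what the fusion transgene changed in HSPCs. Genes of neutrophil granules rose and genes of stem cells fell. The libraries are bulk RNA of sorted cells, so in each comparison a different mix of cells cannot be told apart from a change within cells. S100a8 (ENSMUSG00000056054) and S100a9, whose products form the calcium-binding complex calprotectin of neutrophils and monocytes, rose 55.5-fold (log2 5.79 ± 0.20, adjusted p = 1.84e-10) and 81.0-fold (log2 6.34 ± 0.20, adjusted p = 1.30e-10). S100a8 went from 381 ± 83.3 to 21169.8 ± 3934 CPM and S100a9 from 214 ± 49.3 to 17343 ± 3382 CPM. Flt3, the cytokine receptor of early progenitors, fell from 122 ± 3.71 to 1.05 ± 0.218 CPM (log2 -6.84 ± 0.12, adjusted p = 9.39e-19), and Cd34, a surface marker of progenitors, fell with it (log2 -4.94 ± 0.07, adjusted p = 1.20e-19).

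All 29 genes of the neutrophil list rose (29 also when adjusted over the list alone; median log2 2.88, list adjusted p = 1.40e-27). Among them were Camp, which encodes the antimicrobial peptide cathelicidin (log2 7.40 ± 0.11), Ngp (log2 6.81 ± 0.11), Fcnb (log2 6.30 ± 0.07) and the lactoferrin gene Ltf (log2 5.67 ± 0.10). The largest rises outside the lists included Stfa1 (log2 10.75 ± 0.19), a stefin gene whose family members share reads and whose value is uncertain for that reason, and Hoxc5. Hoxc5 stood at 11.4 ± 0.125 CPM in NHD13 with no count in WT, at least 279-fold higher against a floor of 3 counts over the group. Of 23 stem cell genes 22 fell and 1 did not pass (22 adjusted over the list alone, median log2 -3.95, list adjusted p = 6.74e-14). Among them were Angpt1 (log2 -4.09 ± 0.11) and Meis1, a homeobox gene of stem cells (log2 -4.89 ± 0.12). Lysmd2 (log2 -8.26 ± 0.40), Esam (log2 -7.27 ± 0.35), Maged1 (log2 -7.00 ± 0.25) and the lymphoid polymerase gene Dntt (log2 -6.39 ± 0.16) were among the largest falls.

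Erythroid and heme genes rose by smaller steps. Of 32 erythroid genes 23 rose, 5 fell and 4 did not pass (28 passed adjusted over the list alone, list adjusted p = 1.46e-05, but adjusted p = 0.0524 with an estimated correlation). Rhag, part of the red cell Rh complex, rose (log2 1.45 ± 0.08), as did the alpha-globin gene Hba-a1 (log2 1.14 ± 0.08), while the transcription factor genes Bcl11a, Nfe2, Zfpm1 and Tal1 and the beta-globin gene Hbb-bt fell. Of 20 genes of heme synthesis and iron handling 16 rose and 4 did not pass (16 adjusted over the list alone, list adjusted p = 2.87e-06). They included Alas1, which makes the first committed step of the pathway (log2 1.96 ± 0.07), and Fech, which makes the last (log2 1.17 ± 0.07). All 24 G2/M genes rose (24 adjusted over the list alone, list adjusted p = 1.45e-14), with Ube2c (log2 1.67 ± 0.07) and the cyclin gene Ccna2 (log2 1.17 ± 0.06). In the S phase list 17 rose, 1 fell (Ung) and 6 did not pass (19 passed adjusted over the list alone, list adjusted p = 9.27e-06), with the ribonucleotide reductase gene Rrm2 at 1.5 ± 0.05.

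The Hox-Meis list was called up, with 12 genes rising, 3 falling and 3 not passing (15 passed adjusted over the list alone, list adjusted p = 0.00443). Pbx3, a partner of Hox proteins, rose (log2 2.90 ± 0.10), but Flt3 and Meis1, which the list holds as parts of the same program, fell. Lists of several other lineages were called down. Of 20 megakaryocyte and platelet genes 16 fell and 3 (Fli1, Cd9 and Thbs1) rose (19 passed adjusted over the list alone, list adjusted p = 1.46e-05). Pf4 was at -2.46 ± 0.08 and Itga2b at -3.46 ± 0.15. Of 19 dendritic cell genes 17 fell and 1 (Zbtb46) rose (18 passed adjusted over the list alone, list adjusted p = 8.27e-09). The antigen presentation genes Cd74 (log2 -2.62 ± 0.08) and H2-Eb1 (log2 -3.28 ± 0.12) were among those that fell. In the T and NK cell list 13 fell and 2 (Nkg7 and Cd3d) rose (16 passed adjusted over the list alone, list adjusted p = 0.00159). Lat was at -3.16 ± 0.16 and Nkg7 at 1.28 ± 0.06. In the stroma and endothelium list 8 fell and 2 (Acta2 and Cxcl12) rose (10 passed adjusted over the list alone, list adjusted p = 0.0192, but adjusted p = 0.0650 with an estimated correlation). Pdgfrb was at -2.90 ± 0.14.

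In the interferon list 18 of 28 genes fell, with Ifitm3 at -1.77 ± 0.05, and 7 rose, with the chemokine gene Cxcl10 at 2.08 ± 0.09 (25 passed adjusted over the list alone, list adjusted p = 0.0419, but adjusted p = 0.0747 with an estimated correlation). Immediate early and heat shock genes, which respond to the handling of cells, fell in 18 of 20 cases (18 adjusted over the list alone, list adjusted p = 4.34e-08, but adjusted p = 0.0747 with an estimated correlation). Fos was at -1.95 ± 0.09 and Atf3 at -1.96 ± 0.09. The remaining 10 lists were not called. Of 22 monocyte and macrophage genes 6 rose and 14 fell (21 passed adjusted over the list alone, list adjusted p = 0.0995). Among 24 TLR4 and NF-kappaB response genes 7 rose and 9 fell (17 passed adjusted over the list alone, list adjusted p = 0.725). Rises among 20 mast cell, basophil and eosinophil genes numbered 7, and falls 10 (17 passed adjusted over the list alone, list adjusted p = 0.534). Of 18 B cell genes 1 rose and 10 fell (11 passed adjusted over the list alone, list adjusted p = 0.0843). Among 29 H3K36 and DNA methylation genes 4 rose and 12 fell (16 passed adjusted over the list alone, list adjusted p = 0.197). Rises among 21 p53 response genes numbered 3, and falls 11 (17 passed adjusted over the list alone, list adjusted p = 0.197).

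Of 14 mitochondrially encoded genes 1 rose and 2 fell (2 passed adjusted over the list alone, list adjusted p = 0.595). Among 78 cytosolic ribosomal protein genes 2 rose and 4 fell (2 passed adjusted over the list alone, list adjusted p = 0.692). Rises among 19 glycolysis and hypoxia genes numbered 11, and falls 5 (16 passed adjusted over the list alone, list adjusted p = 0.0551). Of 28 leukemia-associated genes 9 rose and 13 fell (23 passed adjusted over the list alone, list adjusted p = 0.685). In the last list Igf2bp3, an RNA-binding protein of fetal blood cells, rose (log2 4.91 ± 0.13), as did Prom1, the gene of CD133 (log2 3.50 ± 0.13).

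Of 16233 genes tested, 4112 rose and 4652 fell in NHD13, and 1160 and 2579 did so by at least 2-fold. On log2(FPKM + 1) values, which carry no correction for composition, 1683 rose and 8305 fell, and with upper-quartile factors 3368 rose and 5298 fell. The median of all genes lay at -0.04 with the main scaling, at -0.12 with upper-quartile factors and at -0.36 on log2(FPKM + 0.1) values. The 10 most abundant genes took 14.1% to 15.8% of the counts in NHD13 against 6.90% to 7.16% in WT. No called list changed direction between these scalings.

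**Figure D2:**
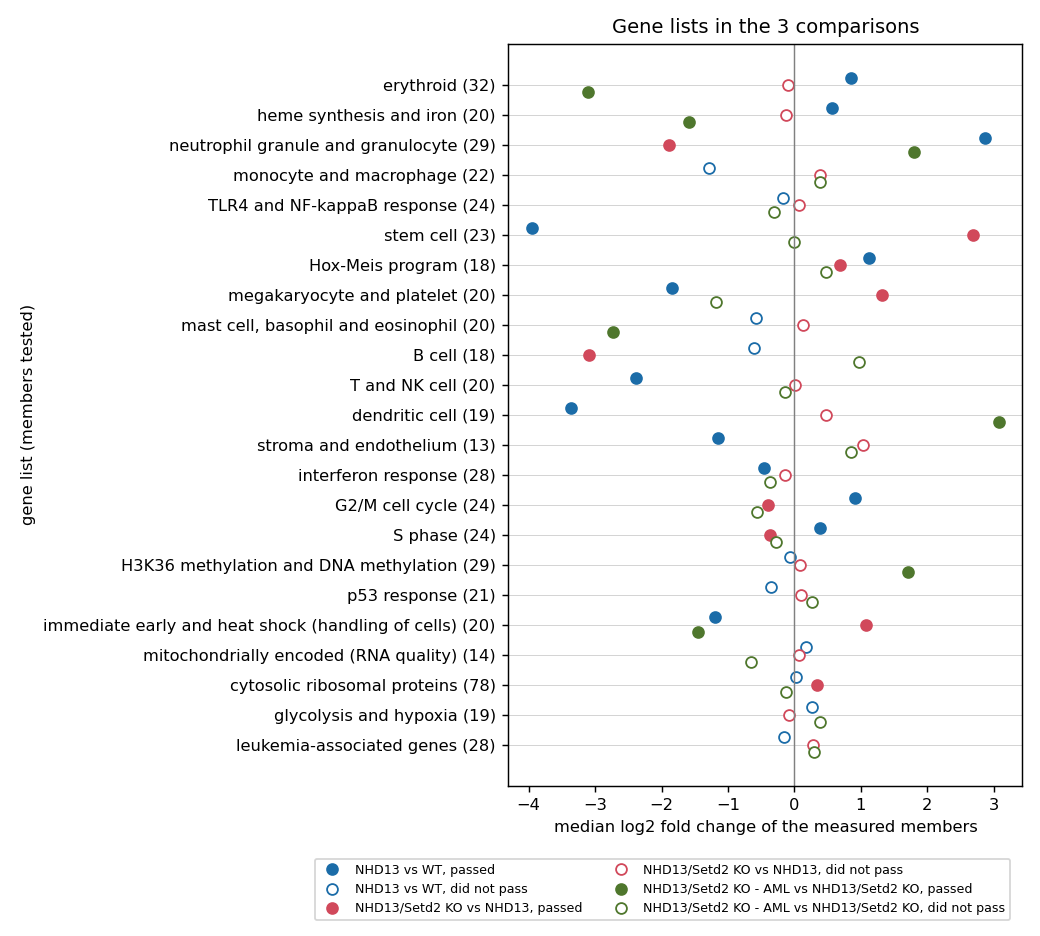
Median log2 fold change of the tested members of each of the 23 fixed gene lists in the 3 comparisons, with filled points for lists that passed the camera test. The neutrophil list is at 2.88 in NHD13 against WT and -1.89 in the libraries labelled KO against NHD13, and the stem cell list at -3.95 and 2.69.

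The comparison of the libraries labelled KO with NHD13 asked what loss of Setd2 added to the transgene. In the direction the labels give, genes of neutrophil granules fell and stem cell genes rose. S100a8 and S100a9 fell 10.2-fold (log2 -3.35 ± 0.18, adjusted p = 1.82e-08) and 13.8-fold (log2 -3.79 ± 0.18, adjusted p = 8.65e-09), to 2072 ± 237 and 1256 ± 82.2 CPM. Flt3 rose from 1.05 ± 0.218 to 34.8 ± 3.21 CPM (log2 5.03 ± 0.12, adjusted p = 3.01e-16), and Cd34 rose with it (log2 3.54 ± 0.07, adjusted p = 2.63e-17). The libraries differed in sex: Xist, the RNA that silences an X chromosome in females, averaged 185 CPM (for sex-linked genes per library total, without TMM factors) in WT and 77.0 CPM in NHD13 but 0.059 CPM in the libraries labelled KO and 0.017 CPM in AML. The Y-linked gene Eif2s3y averaged 0.013 CPM in NHD13 and 55.6 CPM in the libraries labelled KO, so sex and the KO label cannot be told apart in any gene of this comparison.

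All 29 neutrophil genes fell (29 adjusted over the list alone, median log2 -1.89, list adjusted p = 4.79e-29). They included Ngp (log2 -5.18 ± 0.10), Chil3 (log2 -5.08 ± 0.11), Camp (log2 -4.81 ± 0.09) and Ltf (log2 -4.27 ± 0.09). Orm1, an acute phase protein gene, and Afap1 were among the largest falls (log2 -5.87 ± 0.25 and -5.56 ± 0.19). Of 23 stem cell genes 17 rose and 6 did not pass (17 adjusted over the list alone, median log2 2.69, list adjusted p = 1.03e-10), including Angpt1 (log2 3.31 ± 0.11) and Meis1 (log2 3.40 ± 0.12). Ctla2a (log2 5.32 ± 0.10) and the melanocortin receptor gene Mc5r (log2 5.0 ± 0.10) were among the largest rises. In the Hox-Meis list 11 genes rose, with Pbx3 (log2 1.02 ± 0.08) and Hoxa9 (log2 0.68 ± 0.06), and 1 fell (12 passed adjusted over the list alone, list adjusted p = 2.59e-04). Of 20 megakaryocyte and platelet genes 16 rose, with Pf4 at 3.64 ± 0.09, and 3 (Fli1, Cd9 and Thbs1) fell, with Thbs1 at -2.03 ± 0.11 (19 passed adjusted over the list alone, list adjusted p = 1.46e-05).

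B cell genes fell in 17 of 18 cases and Rag2 rose (18 passed adjusted over the list alone, median log2 -3.09, list adjusted p = 6.05e-09). The B cell receptor gene Cd79a (log2 -4.02 ± 0.17) and the surrogate light chain genes Vpreb3 (log2 -6.21 ± 0.29) and Igll1 (log2 -4.87 ± 0.24) were among them. In the G2/M list 23 of 24 genes fell (23 adjusted over the list alone, median log2 -0.39, list adjusted p = 1.99e-09), with Ccnb2 (log2 -0.54 ± 0.05) and Cdk1 (log2 -0.61 ± 0.06). In the S phase list 18 of 24 fell (21 adjusted over the list alone, list adjusted p = 3.60e-07), with Rrm2 (log2 -1.13 ± 0.05). Cytosolic ribosomal protein genes rose in 53 of 78 cases and 25 did not pass (58 adjusted over the list alone, median log2 0.34, list adjusted p = 8.27e-09, but adjusted p = 0.527 with an estimated correlation). Among them were Rps19, a gene mutated in Diamond-Blackfan anemia (log2 0.67 ± 0.08), and Rpl29 (log2 1.25 ± 0.09), which shares reads with processed copies and is uncertain. Immediate early and heat shock genes rose in 17 of 20 cases and Hspa1b fell (18 passed adjusted over the list alone, list adjusted p = 4.70e-09, but adjusted p = 0.0616 with an estimated correlation). Nr4a1 was at 3.26 ± 0.15 and Dusp2 at 1.56 ± 0.06.

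The erythroid list was not called: 5 of its 32 genes rose, 10 fell and 17 did not pass (15 passed adjusted over the list alone, median log2 -0.09, list adjusted p = 0.577). Mybl2, a cell cycle regulator (log2 -0.99 ± 0.13), and Add2, the gene of red cell beta-adducin (log2 -0.60 ± 0.10), were among those that fell. Heme synthesis and iron genes were not called either (4 rose, 7 fell, 11 passed adjusted over the list alone, list adjusted p = 0.489), although Alas1 fell (log2 -1.08 ± 0.07). In the monocyte and macrophage list 10 rose, with the chemokine receptor gene Ccr2 (log2 2.85 ± 0.09), and 10 fell, with the lysozyme gene Lyz2 (log2 -2.33 ± 0.07; 20 adjusted over the list alone, list adjusted p = 0.50). In the TLR4 and NF-kappaB list, the receptor pathway that calprotectin can engage, 7 rose, with Ccl4 (log2 1.44 ± 0.07), and 5 fell, with Il1b (log2 -2.88 ± 0.13; 12 adjusted over the list alone, list adjusted p = 0.743). In the p53 list 7 rose, with the cell cycle inhibitor gene Cdkn1a (log2 2.29 ± 0.09), and 3 fell (10 passed adjusted over the list alone, list adjusted p = 0.155). In the leukemia list 15 rose and 6 fell, with Prom1 at -2.51 ± 0.12 (22 passed adjusted over the list alone, list adjusted p = 0.0680).

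The other lists were not called. Of 20 mast cell, basophil and eosinophil genes 9 rose and 8 fell (17 passed adjusted over the list alone, list adjusted p = 0.581). Among 20 T and NK cell genes 3 rose and 3 fell (5 passed adjusted over the list alone, list adjusted p = 0.988). Rises among 19 dendritic cell genes numbered 6, and falls 3 (12 passed adjusted over the list alone, list adjusted p = 0.230). Of 13 stroma and endothelium genes 4 rose and 1 fell (5 passed adjusted over the list alone, list adjusted p = 0.0803). Among 28 interferon response genes 8 rose and 7 fell (17 passed adjusted over the list alone, list adjusted p = 0.795). Rises among 29 H3K36 and DNA methylation genes numbered 9, and falls 4 (13 passed adjusted over the list alone, list adjusted p = 0.437). Of 14 mitochondrially encoded genes 0 rose and 0 fell (0 passed adjusted over the list alone, list adjusted p = 0.768). Among 19 glycolysis and hypoxia genes 3 rose and 7 fell (10 passed adjusted over the list alone, list adjusted p = 0.0843).

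Of 16233 genes 3340 rose and 3295 fell, and 1407 and 1051 did so by at least 2-fold; on log2(FPKM + 1) values 4935 rose and 1932 fell. The median of all genes on log2(FPKM + 0.1) values was 0.17.

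Most genes called in both comparisons of HSPCs moved one way with the transgene and the other way in the libraries labelled KO. Of the genes called in both comparisons, 2490 rose in NHD13 and then fell (835 by independent lists) and 2450 fell and then rose (957 by independent lists), while 135 rose in both (846) and 176 fell in both (944). Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was -0.63 and Spearman's rho -0.67. The NHD13 libraries enter both comparisons with opposite sign, and 20 simulations with no effect at all gave a mean r of -0.54. The covariance was -1.02 against -0.10 in the simulations, a difference of -0.93. With separate NHD13 libraries for each comparison, in all 6 ways (chosen after the data were seen), r was -0.51 to -0.50 and the covariance -1.03 to -0.97. A deviation common to the 3 NHD13 libraries would still enter both comparisons.

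The comparison of AML with the libraries labelled KO set leukemia-stage spleen cells against bone marrow HSPCs, so disease stage, organ and sorted population changed together. Erythroid genes fell, while dendritic cell genes, those of antigen presentation among them, and most genes of H3K36 and DNA methylation rose. Car1 and Car2, carbonic anhydrases of red cells, fell (log2 -8.34 ± 0.12, adjusted p = 1.95e-19, and -5.91 ± 0.10, adjusted p = 5.70e-19), as did Klf1, the master regulator of the erythroid lineage (log2 -6.34 ± 0.11, adjusted p = 5.61e-19). H2-Eb1, of MHC class II, rose 155-fold (log2 7.28 ± 0.11, adjusted p = 3.09e-19). S100a8 stood at 2707 ± 129 CPM in AML against 2072 ± 237 (log2 0.39 ± 0.16, adjusted p = 0.0437) and S100a9 at 2832 ± 44.2 against 1256 ± 82.2 CPM (log2 1.17 ± 0.16, adjusted p = 3.41e-05). The S100a8 call was lost with RLE factors (adjusted p = 0.0546), upper-quartile factors (0.313), no filter (0.117), a replicate block (0.0568) and DESeq2 (0.0603), and without replicate 2 (0.124) or 3 (0.101) of the libraries labelled KO or replicate 1 (0.0862), 2 (0.0532) or 3 (0.101) of AML.

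Of 32 erythroid genes 25 fell, with Blvrb (log2 -5.28 ± 0.08) among them, and 7 rose, Hbb-bt, Tfrc, Bcl11a, Mybl2, Tal1, Slc4a1 and Sptb (32 passed adjusted over the list alone, median log2 -3.10, list adjusted p = 4.16e-06). Of 20 heme synthesis and iron genes 14 fell, with the ferritin heavy chain gene Fth1 (log2 -3.89 ± 0.07), and 3 rose, Slc25a37, Ireb2 and Aco1 (17 passed adjusted over the list alone, list adjusted p = 0.00100). In the neutrophil list 22 genes rose, with Ltf (log2 4.73 ± 0.09), the granulocyte regulator gene Cebpa (log2 4.66 ± 0.09) and Cd177 (log2 5.02 ± 0.11). Against the list 7 fell (29 passed adjusted over the list alone, median log2 1.81, list adjusted p = 0.00436, but adjusted p = 0.150 with an estimated correlation). Those that fell were Igsf6, Ms4a3, Retnlg and the primary granule genes Elane, Mpo, Ctsg and Prtn3, with Elane going from 19332 ± 1671 to 2478 ± 61.3 CPM (log2 -2.96 ± 0.08). Of 19 dendritic cell genes 13 rose, with Itgax, the gene of CD11c (log2 8.58 ± 0.22), and Cd74 (log2 5.22 ± 0.09), and 3 fell, Bst2, Tcf4 and Siglech (16 passed adjusted over the list alone, median log2 3.08, list adjusted p = 0.00677). Mast cell, basophil and eosinophil genes fell in 15 of 20 cases, with Cpa3 (log2 -5.50 ± 0.12) and Gzmb (log2 -7.55 ± 0.20), and 2 rose, Il5ra and Il6ra (Il6ra log2 3.53 ± 0.13; 17 passed adjusted over the list alone, list adjusted p = 0.00129, but adjusted p = 0.0563 with an estimated correlation).

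Of 29 H3K36 and DNA methylation genes 25 rose and 2 (Psip1 and Mtf2) fell (28 passed adjusted over the list alone, median log2 1.72, list adjusted p = 2.20e-06). Nsd2, which dimethylates H3K36 (log2 2.26 ± 0.06), and the elongation factor gene Supt6 (log2 2.34 ± 0.08) rose with Setd2. These are long genes, and in AML long genes were higher and short ones lower across the whole transcriptome: the median log2 fold change went from -1.05 in 1810 genes under 1000 bp to 0.97 in 2136 genes over 8000 bp. Spearman's rho across genes was 0.31, against -0.01 and 0.01 in the other comparisons. With the length correction the list median was 1.05. Under that correction all 35 named genes of this comparison kept their direction and passed, but 18 moved by over 1.5-fold, with shifts of -1.04 to 1.05 on the log2 scale. S100a8 and S100a9 stood at 1.40 and 2.22. Immediate early and heat shock genes fell in 17 of 20 cases, with Klf6 (log2 -3.27 ± 0.06) and Ier3 (log2 -3.31 ± 0.08), and Fosb, Hspa1b and Jun rose (20 passed adjusted over the list alone, list adjusted p = 6.56e-04, but adjusted p = 0.244 with an estimated correlation).

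**Figure D3:**
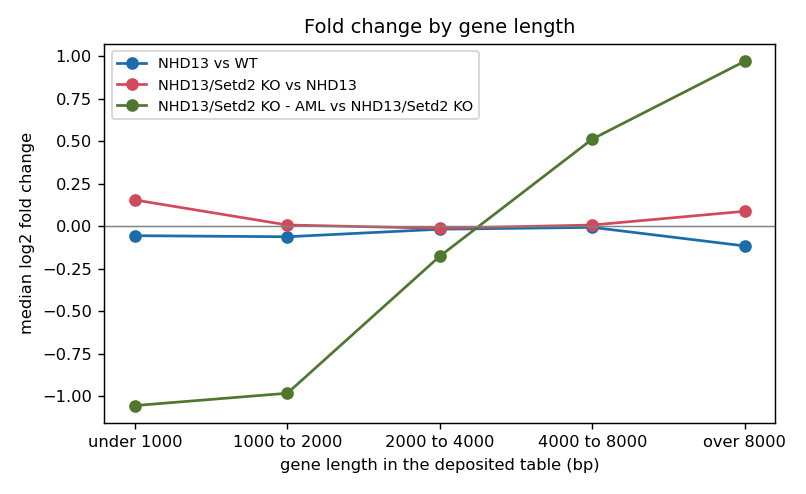
Median log2 fold change of tested genes by gene length in the 3 comparisons. In AML against the libraries labelled KO the median rises from -1.05 under 1000 bp to 0.97 over 8000 bp, and in the other comparisons it stays between -0.12 and 0.15.

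The remaining lists were not called. In the megakaryocyte list 13 fell, with Pf4 at -6.99 ± 0.11, and 3 rose, with Thbs1 at 4.83 ± 0.10 (17 passed adjusted over the list alone, list adjusted p = 0.0562). In the leukemia list 14 rose, with Cd33 (log2 3.78 ± 0.09) and Erg (log2 3.27 ± 0.08), and 4 fell (18 passed adjusted over the list alone, list adjusted p = 0.101). In the Hox-Meis list 11 rose, with Hoxa3 at 4.04 ± 0.22, and 7 fell (18 passed adjusted over the list alone, list adjusted p = 0.595). The chemokine genes Cxcl10 (log2 -7.69 ± 0.15) and Ccl4 (log2 -6.83 ± 0.10) fell within uncalled lists. Of the interferon response genes 13 rose and 14 fell (27 passed adjusted over the list alone, list adjusted p = 0.850). Of the TLR4 and NF-kappaB response genes 8 rose and 13 fell (21 passed adjusted over the list alone, list adjusted p = 0.230).

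Of 22 monocyte and macrophage genes 12 rose and 7 fell (19 passed adjusted over the list alone, list adjusted p = 0.577). Among 23 stem cell genes 8 rose and 9 fell (17 passed adjusted over the list alone, list adjusted p = 0.782). Rises among 18 B cell genes numbered 7, and falls 4 (11 passed adjusted over the list alone, list adjusted p = 0.576). Of 20 T and NK cell genes 7 rose and 7 fell (14 passed adjusted over the list alone, list adjusted p = 0.874). Among 13 stroma and endothelium genes 6 rose and 2 fell (8 passed adjusted over the list alone, list adjusted p = 0.261).

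Of 24 G2/M genes 7 rose and 16 fell (23 passed adjusted over the list alone, list adjusted p = 0.0526). Among 24 S phase genes 7 rose and 12 fell (19 passed adjusted over the list alone, list adjusted p = 0.12). Rises among 14 mitochondrially encoded genes numbered 1, and falls 8 (9 passed adjusted over the list alone, list adjusted p = 0.170). Of 78 cytosolic ribosomal protein genes 25 rose and 36 fell (61 passed adjusted over the list alone, list adjusted p = 0.419). Among 19 glycolysis and hypoxia genes 10 rose and 9 fell (19 passed adjusted over the list alone, list adjusted p = 0.874). In the p53 list 10 rose and 10 fell (20 passed adjusted over the list alone, list adjusted p = 0.871), and its median of 0.26 and the direction of the test, down, differed in sign.

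Single genes marked the size of this difference. The zinc finger gene Zic1 was at 37.4 ± 2.55 CPM in AML with no count in the libraries labelled KO, at least 826-fold higher, and Slc25a21 was at least 652-fold lower. Dnase1l3 (log2 10.19 ± 0.32), Tbc1d9 (log2 10.01 ± 0.30) and the nucleic acid sensor gene Tlr9 (log2 8.96 ± 0.40) were among the largest rises and Vill (log2 -9.82 ± 0.31) among the largest falls. Of 16233 genes 6953 rose and 6415 fell, and 5055 and 4363 did so by at least 2-fold; on log2(FPKM + 1) values 8437 rose and 4953 fell. The median of all genes was 0.42 on log2(FPKM + 0.1) values and -0.11 with upper-quartile factors.

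H3K36me3 peaks were fewer and shorter in the leukemia-stage cells labelled Setd2 KO than in those labelled NHD13. The list of NHD13-AML held 30953 broad peaks over 193.0 Mb with a median length of 2503 bp, and that of NHD13/Setd2 KO-AML 16902 peaks over 28.4 Mb with a median of 1101 bp. Peaks of 10 kb or more numbered 5498 and 154. Of the NHD13-AML peaks 24.1% (Wilson 95% interval 23.6 to 24.6, counting error only) were overlapped by at least 1 bp, and 2.80% over at least 50% of their length, while 88.2% of the KO-AML peaks overlapped a peak of NHD13-AML. With the same number of top peaks by score in both lists the first share was 40.2%. Each list comes from 1 library, so no test between the groups can be made, and the input and depth of the ChIP libraries are not given in the sources used here, so a weaker ChIP would give fewer and shorter peaks too. Most peaks lay in protein-coding genes (94.0% and 90.1%), and their scores and folds (median 4.41 and 4.90) are the authors'.

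Among 14357 tested genes with coordinates, 3960 had a peak in NHD13-AML only, 5969 in both lists, 185 in KO-AML only and 4243 in neither. Where NHD13-AML had a peak, the median share of the gene body inside peaks was 60.5% there and 2.49% in KO-AML. For Setd2 itself the share went from 90.5% to 22.5%, for the primary granule gene Mpo from 92.1% to 73.9%, and for Elane, Camp and S100a9 from 75.6%, 53.3% and 48.0% to 0. S100a8 had no peak in either list. Genes of S phase (median 88.7% and 35.8%), G2/M (86.2% and 20.7%) and cytosolic ribosomal proteins (62.2% and 40.9%) had part of their bodies inside peaks in both lists, while the median of the neutrophil list went from 64.2% to 0 and that of heme synthesis and iron from 49.9% to 0. Erythroid and stem cell lists had a median of 0 in both. The progenitor genes Cd34 and Gata2 had more of their body inside peaks in KO-AML, going from 5.50% to 15.3% and from 0 to 23.0%.

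**Figure D4:**
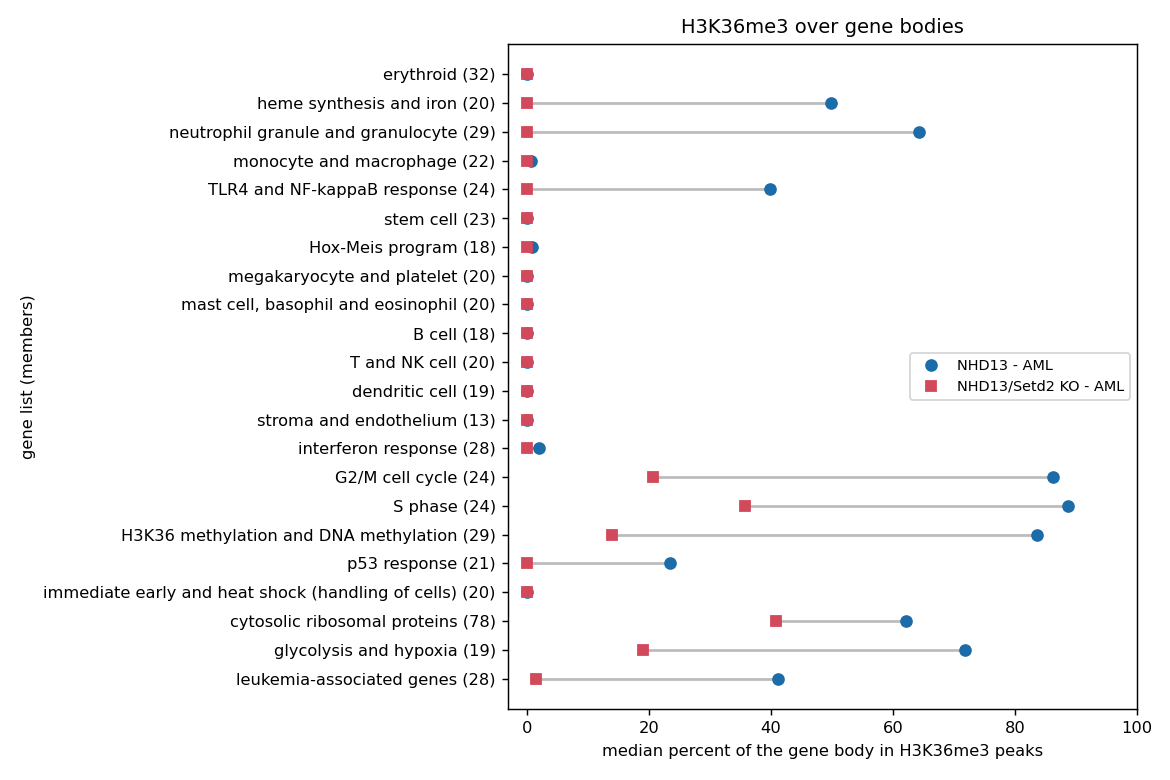
Median percent of the gene body inside H3K36me3 peaks for the members of each gene list, in NHD13-AML and NHD13/Setd2 KO-AML (1 library each, so no error). The share is lower in KO-AML for each list above 0 in NHD13-AML, for example 88.7% against 35.8% for S phase genes.

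Genes with a peak in NHD13-AML only differed little in RNA from those with a peak in both lists. In the libraries labelled KO against NHD13 their median log2 fold changes were -0.09 (3960 genes) and 0.00 (5969 genes), a difference of -0.09 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give; genes are not independent replicates). The mark was profiled at the leukemia stage and the RNA before it, and genes with a peak in NHD13-AML only were less expressed (median 13.1 against 41.7 CPM). Matched on mean expression the difference was -0.14. A further setting grouped genes otherwise, among those with at least 20% of the body inside NHD13-AML peaks. It set 7272 genes with under 50% of these bases also in KO-AML peaks against the remaining 985. There the difference was -0.12 (the same permutation test, p = 1e-05 for both settings).

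The authors' deposited table of differentially methylated regions (DMRs) for WT and NHD13 held mostly regions lower in NHD13: 47903 of 58684 (81.6%), with 10781 higher. The mean level over its regions was 72.8% in WT and 53.8% in NHD13. In the authors' deposited table for NHD13 and the KO label the direction turned, with 29052 of 37430 regions higher and 8378 lower in KO, and means of 54.3% and 69.2%. In the authors' deposited table for KO and AML 82461 of 106032 regions were lower in AML and 23571 higher, with means of 72.9% and 53.1%. Each library is 1 sample, the files hold no coverage, and the depth is unknown, so neither a test nor an interval can be given. Regions on X numbered 1780, 4832 and 7962 and regions on Y 22, 53 and 1730, and sex may differ between these libraries as it does in the RNA. The larger number on Y for KO and AML would be seen if these libraries, but not NHD13, carried a Y. Without coverage this cannot be decided.

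Over S100a8 (chromosome 3, 90669071 to 90670034) the authors' deposited tables give a region from 90668993 to 90669916 with 35 CpG sites, which starts outside the annotated gene and covers most of it, at 74.9% in WT and 33.8% in NHD13. The part up to 90669785 (28 CpG sites) was at 25.5% in NHD13, 62.4% in KO and 18.2% in AML, per the authors' deposited tables. At S100a9 the authors' deposited table for NHD13 has 1 region, 90695648 to 90696138, at 70.4% in WT and 39.0% in NHD13, and in KO the nearest region lay 3846 bp away. Camp went from 95.1% to 54.1% (chromosome 9, 109847526 to 109847956) and Mpo from 87.5% to 43.1% (chromosome 11, 87797230 to 87799889) between WT and NHD13 in the same authors' deposited table. Of 29 neutrophil genes, 25 overlapped a region lower in NHD13 than in WT and 2 a higher one, in the authors' deposited tables. For KO against NHD13, 17 overlapped a higher region and 2 a lower one, and for AML against KO 17 a lower and 3 a higher one, in the authors' deposited tables. Among all 14357 tested genes with coordinates, 6001 overlapped a lower region and 2850 a higher one for NHD13. For KO 3733 overlapped a higher and 3631 a lower one, and for AML 4298 a lower and 4280 a higher one. The difference between the list and all genes was not tested. Meis1 went the other way from the neutrophil genes: 19006411 to 19014551 on chromosome 11 (326 CpG sites) was at 14.8% in WT and 66.1% in NHD13 in the authors' deposited table. At its upper end, 19013296 to 19014551 was at 50.2% in NHD13 and 17.9% in KO, and 19013296 to 19015537 was at 13% in KO and 88.4% in AML, per the authors' deposited tables. Car2 (chromosome 3, 14887878 to 14892030) went from 15.3% in WT to 57.2% in NHD13, and H2-Eb1 (chromosome 17, 34309286 to 34310095) from 54.7% in KO to 96.0% in AML, in the authors' deposited tables. Exon and intron positions were not used here.

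Genes with a region higher in methylation tended to be among those that fell, and genes with a lower region among those that rose, in the comparisons of HSPCs. For NHD13 against WT the odds ratios (Fisher's exact test over genes, two-sided, adjusted over 12 tests) were 2.16 for higher and fell (adjusted p = 3.28e-67) and 1.5 for lower and rose (adjusted p = 1.38e-26); within tertiles of gene length they were 1.94 and 1.62. For the KO label against NHD13 they were 1.84 (adjusted p = 5.03e-43) and 1.58 (adjusted p = 6.57e-24). The opposite pairings changed with the setting. In NHD13 higher and rose was 0.704 (1.25 for genes changed by at least 2-fold) and lower and fell 1.19 (0.949 within length tertiles), and for the KO label higher and rose was 1.19 (0.982 within length tertiles) and lower and fell 0.899 (adjusted p = 0.0233, and 0.916 with adjusted p = 0.0740 without X and Y). Among genes changed by at least 2-fold the KO label gave 3.59 for higher and fell and 1.25 for lower and rose, but also 1.90 for higher and rose (adjusted p = 1.99e-23), with 0.557 for lower and fell. For AML against KO the odds ratios were 1.52 for higher and rose, 0.636 for higher and fell, 1.79 for lower and rose and 0.519 for lower and fell, and within length tertiles 1.09, 0.863, 1.23 and 0.722.

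Regions lower in KO overlapped H3K36me3 peaks of NHD13-AML more often than regions higher in KO (odds ratio 13.4, 1 library each). On autosomes 35.1% of the 6769 regions lower in KO than in NHD13 and 3.87% of the 25716 higher ones overlapped such a peak. For NHD13 against WT the shares were 6.96% and 8.11%, and for AML against KO 2.19% and 8.86%, from the authors' deposited tables of regions and peaks.

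**Figure D5:**
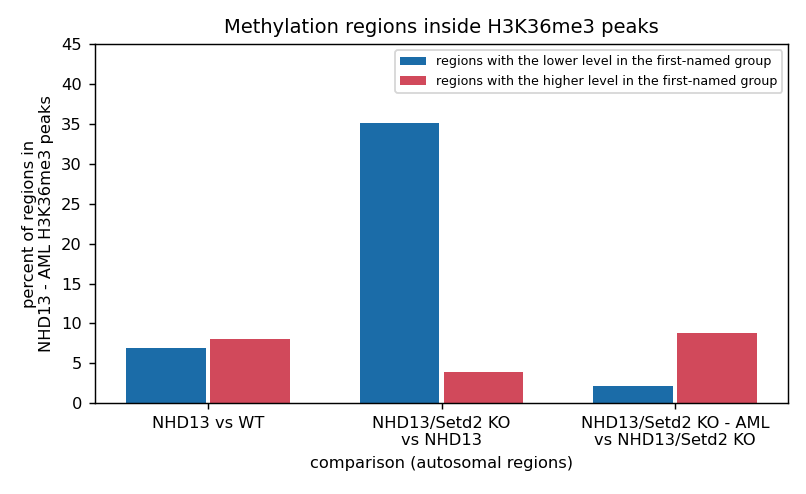
Percent of autosomal regions of the authors' deposited tables that overlap an H3K36me3 peak of NHD13-AML, for regions lower and higher in the first-named library of each comparison. For KO against NHD13 the shares are 35.1% and 3.87%.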

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

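In this part the length correction and the tests of RNA selection, scaling, late neutrophil genes, exchanged labels, sex, shared immunoglobulin segments and index hopping were chosen after the result was seen. Groups of 3 were not tested for outliers.

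Genes of 4000 bp and over took 51.3% to 51.9% of the counts in AML against 27.6% to 35.2% in the other libraries, and short genes were lower to match. Gene length bias as the whole cause is not decided by the gene calls. After a length correction 87.8% of them were still made, in either direction, but 13003 of all 16233 genes were called then. That share is not far above what any set of genes would give. The rise of the H3K36 and DNA methylation list kept an adjusted p of 0.00174 (camera), which argues against length bias as its whole cause. The list median went from 1.72 to 1.05 (SD 1.05 and 1.12 over genes). Against a few abundant short genes losing counts, 1551 genes under 1000 bp with below-median expression had a median log2 fold change of -0.82 (bootstrap 95% interval -0.95 to -0.69). The 256 genes of that length with above-median expression were lower still, with a median of -1.96. A difference in RNA selection stays open: histone genes, whose transcripts lack a poly(A) tail, had a median log2 fold change -0.76 relative to that of S phase genes, each against genes of like length (bootstrap 95% interval -1.28 to 0.19), which does not decide. That explanation cannot be told apart from a difference between spleen and marrow cells, because all AML libraries differ from the rest in organ, stage and sort.

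S100a8, S100a9 and granule genes were lower in the libraries labelled KO than in NHD13. The choice among 8 scalings did not account for this, as S100a8 stayed at -3.16 or below (lowest -3.52). The median of all genes was 0.02 with TMM and RLE factors, 0.09 with upper-quartile factors and 0.17 on log2(FPKM + 0.1) values. Scalings this alike could not have removed such a fall, so they do not test library composition further. Mature neutrophils carried into the NHD13 sort stay open: 5 late genes (Retnlg, Mmp9, Cxcr2, Ly6g and Mmp8, median -1.83, range -3.52 to -1.51) fell about as far as the other 24 genes of the neutrophil list (median -1.90, range -5.18 to -0.33), a difference of 0.063 that does not decide. Exchanged labels of the RNA libraries stay open, since Setd2 differed by only -0.05, as with an exon deletion that counts do not see. The peaks (28.4 Mb in KO-AML against 193.0 Mb, as a weaker ChIP would also give) ran the way of their labels, but are other libraries. The odds ratio of 13.4 for regions lower in the bisulfite library of KO to lie in peaks does not check its label. Reading it so assumes that DNA methylation is lost with H3K36me3, which is only a hypothesis here. Sex is confounded with the KO label: 6445 genes were called without X and Y, and an indirect effect of sex, like one of Setd2, remains untested.

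Immunoglobulin V segments marked groups rather than libraries: of 20 cases of a segment at 5 CPM or more (per library total) in a library of a group, 12 were below 1 CPM in each library of the other groups, and 10 of these were at 1 CPM or more in all 3 libraries of their group. Igkv14-130, for example, was at 26.2 to 37.6 CPM in the libraries labelled KO. For NHD13, KO and AML (8 of 8) this could come from 3 libraries of 1 animal or pool, since B cell clones differ between animals. The limit of 1 CPM does not see differences in level, however. In NHD13 Igkv3-10 ran from 8.81 to 32.3 CPM and Igkv10-96 from 2.91 to 9.76 CPM, while Ighv1-54 ran from 8.12 to 11.6 CPM. Against 1 pool of RNA for WT, 2 of its 4 private segments (Igkv12-89 and Igkv1-117) had no count in replicate 1, while the other 2 were in all 3 libraries, so alleles shared by a strain could also give such sharing. Against index hopping, the lowest library of a group held a median of 0.698 of the highest, and T cell receptor segments could not decide, with 0 private segments found.

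Groups of 3 allow 10 splits of 6 libraries, too few for a share under 0.05. The real split gave 8764, 6635 and 13368 genes and the highest other 245, 0 and 0. Lists adjusted within a comparison numbered 14, 9 and 7 in the real split and 13, 9 and 8 in the highest other. Every other split mixed libraries of both groups, so the group difference entered the residual spread and, in part, the contrast. The other splits therefore do not show what data without an effect would give.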

How the results depend on the processing

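The length correction, the settings without X and Y and the separate NHD13 libraries were chosen after the data were seen, and all other settings before. Of 2031 values of 88 named genes under alternatives, 2021 kept their direction and their side of the threshold, and 10 lost the call, all for S100a8 in AML against the libraries labelled KO (adjusted p 0.0532 to 0.313, 0 reversed), 5 of them by leaving out 1 library. Most of these genes were named for a large change or a small p in the same data, so their stability says little about other calls. Of 158 alternatives of the comparisons themselves 138 gave the same by limits of size or side. For numbers of genes, lists and regions the limit was a total within 1.5-fold, whatever the genes or directions. On log2(FPKM + 1) values NHD13 counted as the same with 1683 genes rising and 8305 falling, against 4112 and 4652. Of its 8764 main calls 6513 were shared. Leaving out 1 library at a time gave 8174 to 9131, 5756 to 6339 and 13128 to 13347 genes and 13 to 15, 9 and 8 to 9 lists. No called list changed direction under any alternative, but the cytosolic ribosomal protein list, not called in NHD13 or AML, was called the other way in both: down in NHD13 without WT replicate 1 (adjusted p = 0.00529) and up in AML with the length correction (adjusted p = 0.00452). On simulated counts, with far fewer genes changed than called in the data, 64% to 68% of 1.5-fold changes were recovered, without varying the depth. The changed genes were above a minimum expected count. The unknown depth of the ChIP and bisulfite libraries leaves their counts of peaks and regions without an error.

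With a threshold of 2-fold the genes called fell to 3739 for NHD13 and 2458 for the KO label, by construction. With an estimated correlation 4 lists were called for AML, in place of 7. With fry, which asks whether the genes of a list move and not whether they move more than others, the KO label gave 18 lists in place of 9 and AML 21 in place of 7. The relation of both HSPC comparisons was -0.75 (Pearson's r) for genes with a mean of at least 10 CPM and -0.65 to -0.64 without 1 of the NHD13 libraries, against -0.63 for all genes; the cause was not tested. With separate NHD13 libraries it was -0.51 to -0.50 (6 ways: 3 times -0.50 with 1 library against WT, and -0.51, -0.50 and -0.51 with 1 against KO); the cause was not tested.

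The share of NHD13-AML peaks overlapped was 18.6% for peaks with a −log10 q of at least 5, 2.80% for an overlap of at least 50% of the peak, 40.2% for the same number of top peaks and 24.7% without X and Y, against 24.1%; a stricter overlap lowers it by construction, and for the others the cause was not tested. Odds ratios between regions and RNA changes turned in 3 cases: for NHD13, lower and fell went from 1.19 to 0.949 within length tertiles and higher and rose from 0.704 to 1.25 with the 2-fold threshold, and for the KO label higher and rose went from 1.19 to 0.982 within length tertiles. The KO label's lower and fell went from 0.899 to 0.916 (adjusted p = 0.0740) without X and Y. The cause was not tested. Tests on promoters were not run, because the gene table gives no strand.

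Replicate numbers are shared between groups. The deviations of same-numbered libraries correlated by -0.38 to 0.54, with 3 of 18 pairs over 0.1 and a median of -0.01, against 0.04 for other numbers. This gives no sign that the numbers pair the samples, but groups of 3 cannot exclude it. Some libraries of other numbers also deviated together or apart, as replicate 1 of WT did with replicates 3 (0.46) and 2 (-0.60) of NHD13. With a replicate block 8568, 6431 and 13238 genes and 14, 9 and 8 lists were called, with 0 list calls lost and 2 gained, and S100a8 in AML lost its call (adjusted p = 0.0568).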

Other observations

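Both tests of methylation at H3K36me3 were set before their results were seen, and the other groups of genes and regions here were chosen after their values were seen.

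Replication-dependent histone genes were not in the fixed lists. Of 55 tested, 9 rose and 20 fell in NHD13 (median log2 -0.17), 12 rose and 2 fell in the libraries labelled KO (0.17), and 2 rose and 46 fell in AML (-2.24), with the TMM scaling only. They are short (median 572 bp), and relative to genes of like length their median in AML was -1.23. They are near-identical copies that share reads, so single members are uncertain.

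In the authors' deposited tables, part of the regions that were lower in NHD13 were higher again in KO. Of the 47903 regions lower in NHD13 than in WT, 10737 (22.4%) were overlapped by a region higher in KO than in NHD13, while 547 were overlapped by a region lower in KO. Of the 10781 regions higher in NHD13, 1406 (13%) were overlapped by a region lower in KO and 985 by a higher one. Both tables share the 1 NHD13 library, so an error in that library alone would give the same picture. Of the cytosolic ribosomal protein genes, 29 of 78 overlapped a region lower in KO than in NHD13 and 1 a higher one. Among all 14357 tested genes with coordinates 3631 overlapped a lower region and 3733 a higher one, and the difference was not tested.

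A hypothesis is that DNA methylation may have been lost in KO where H3K36me3 had been, since DNA methyltransferases of the DNMT3 family bind methylated H3K36. Regions lower in KO than in NHD13 had odds of lying in an H3K36me3 peak of NHD13-AML 13.4 times those of regions higher in KO (autosomes), and 8.72 times within gene bodies. The level the regions start from stays open as a cause, since nearly full methylation can only fall. Among regions with a mean level over both libraries of 40% to 60% the odds ratio was 21.1. In that band regions lower in KO still tend to start higher in NHD13 than the others, so the starting level was not matched and this does not decide. The peaks come from leukemic spleen and the methylation from marrow HSPCs, with 1 library each, so animal, sex and cell type stay open, and for AML against KO the odds ratio was 0.230.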
